A study of Mus musculus with 15 samples.

How the data were processed

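Gene expression was measured in cells sorted from fetal livers of FVB/NJ mouse embryos at embryonic day 14.5. Per the labels' protocols, cells were separated magnetically with beads against TER119, a surface antigen that appears on red cell precursors as they mature. TER119 positive cells were taken by positive selection and TER119 negative cells by depletion. Total RNA was extracted with TRI-Reagent, purified on RNeasy columns, treated with DNase I, labelled with biotin and hybridised to Affymetrix MoGene 1.0 ST arrays, which carry probes along the length of each transcript. The titles in the labels gave 4 groups and the replicate number of each of the 15 arrays. There were 4 wild-type (WT) TER119 negative arrays, 4 Klf3 knockout (KO) TER119 negative arrays, 4 WT TER119 positive arrays and 3 KO TER119 positive arrays. The labels do not say whether the replicates came from separate embryos or litters, so the p-values measure the spread between these samples, which may be partly technical. The number of arrays limits the precision of every value.

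The deposited values were log2 expression per probe set, between 2.91 and 14.26. Per the submitters' processing notes they were made with RMA and Partek, whose versions are not given in the sources used here. RMA subtracts a background, makes the arrays share a distribution and summarises the probes of each probe set, so that differences between dim signals are compressed. Whether all 15 arrays were processed in a single run is not stated. The array names in the labels follow a different pattern in each population. The labels name no batch, and any batch that coincided with the population cannot be told apart from it; the KO comparisons were made within a population. The median log2 value over all probe sets of an array lay between 5.28 and 5.43. No pair of arrays within a group was identical: the smallest standard deviation (SD) of the difference between 2 arrays of a group was 0.259 on the log2 scale.

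The table held 35399 probe sets. The platform's gene table listed 23410 of them, of which 21789 had 1 gene symbol and 1621 had several, and the other 11989 are unnamed here. Of the probe sets with 1 symbol, 21698 had an Entrez identifier in the RefSeq gene table of assembly GRCm38.p6, which was used only for names and for which genes neighbour each other, and which changed 0 symbols. Where a symbol had more than 1 probe set (999 genes), the probe set with the highest mean over all arrays was kept, which left 19938 genes. Probe sets with several symbols or none entered no comparison of genes. The adult alpha and beta globins share such probe sets, so that 6 of the 12 globins listed were measured.

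The comparisons, tests, gene lists, rule for named genes and other settings were fixed before the data were examined. All 15 arrays entered a linear model with a mean per group in limma 3.58.1 under R 4.3.3, without a filter on dim genes and without covariates. The model had 11 residual degrees of freedom, and its empirical Bayes step added 4.91 prior degrees of freedom at a prior SD of 0.173. There were 4 contrasts: KO against WT in TER119 positive cells, KO against WT in TER119 negative cells, the difference between these effects (the interaction), and TER119 positive against TER119 negative cells in WT. Adjusted p-values are limma's moderated test with Benjamini-Hochberg adjustment over the 19938 genes, 2-sided, with a threshold of 0.05. A second count required a 1.5-fold change as well. Errors of differences are standard errors (SE) from the model, and errors of levels are SDs.

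The 23 gene lists were the KLF and SP family, genes reported to be repressed by KLF3, genes reported to be activated by KLF1, globin genes, haem synthesis and iron handling, red cell membrane and cytoskeleton, erythroid transcription regulators, late erythroid clearance and enucleation, cell cycle, ribosomal proteins, p53 target genes, interferon response, haematopoietic progenitor markers, hepatocyte-lineage markers, macrophage markers, neutrophil and granulocyte precursor markers, megakaryocyte and platelet markers, B cell lineage markers, mast cell and basophil markers, T and natural killer cell markers, endothelial markers, stromal and stellate markers, and sex-linked genes. They were written from general knowledge. Of the 34 measured genes of the KLF1-activated list, 28 were also in another list, as were 14 of the 28 red cell membrane genes and 8 of the 29 haem genes, so these lists are not separate measurements. The 21 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over 84 tests of a list in a contrast. Beside it stand camera with the correlation estimated from the data, whose p-values are given unadjusted, and the number of members past the threshold over all genes and adjusted over the list alone. With the estimated correlation, none of the 84 tests passed after adjustment (lowest adjusted p = 0.228). Planned beside these was limma's fry, which tests whether the members of a list change, adjusted over the same tests. Fry called no list in TER119 positive KO-labelled cells (lowest adjusted p = 0.08) or for the interaction (lowest adjusted p = 0.184). In TER119 negative cells it called T and natural killer cell markers alone (adjusted p = 0.0378). For the WT populations most lists passed it, such as KLF1-activated genes (adjusted p = 6.36e-10). The lists with fewer members have counts only.

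The genes shared by both KO comparisons were tested with Fisher's exact test, 2-sided, over all genes; the comparisons share no array. Camera was also run on the 200 genes with the largest difference in favour of TER119 positive cells and the 200 with the largest difference in favour of TER119 negative cells. Among genes past the threshold, these were ranked by the difference between the means of all 7 TER119 positive and all 8 TER119 negative arrays, which is uncorrelated with the KO contrasts. The genes named are Klf3, the genes reported to be repressed by KLF3, every KLF and SP family gene past the threshold, and the 10 with the largest rise and the 10 with the largest fall past the threshold whose arrays do not overlap between groups. To these come the 3 members of each list with the smallest p and up to 3 members of a list of another cell type past the threshold. Sex-linked genes and predicted or unnamed loci were left out of the ranking, and the interaction took 5 genes in each direction. Genes named beyond this rule are said to have been chosen after their values were seen.

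The other settings were quantile normalization again, subtraction of each array's median, filters at the 30th and 50th percentile of mean expression, fits on only the arrays compared, a variance trend with robust estimation, array weights, the mean of a gene's probe sets, the replicate number as a block, the mean of the measured Y-linked genes as a covariate, and each array left out in turn. After seeing the data 3 settings were added: leaving out 3 TER119 negative arrays that stood apart on the first principal component of that population, the mean of the hepatocyte-lineage list as a covariate in each population, and sex read from the arrays as a factor in each population.

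The model was tested on simulated data drawn from the arrays' own means and spreads over 19938 genes with 200 changed genes. For KO against WT in TER119 positive cells it recovered 53.7% of genes changed 1.5-fold, 94.0% of those changed 2-fold and 98.5% of those changed 4-fold. In TER119 negative cells it recovered 58.2%, 98.5% and 100%. For the interaction the shares were 19.4%, 74.6% and 98.5%, and for the populations in WT 55.2%, 95.5% and 100%. False calls numbered 8 in TER119 positive cells, 8 in TER119 negative cells, 9 for the interaction and 6 for the WT populations. The simulated arrays held no structure of the samples beyond their groups. Regrouping the real arrays within a population gave up to 525 genes in TER119 positive and 3563 in TER119 negative cells. The simulated counts of false calls therefore may not hold for the real arrays. A red cell membrane list shifted by 0.30 in simulated TER119 negative cells was recovered by camera with the preset correlation (adjusted p = 1.03e-16) and with an estimated correlation (p = 1.25e-06). Of the 20 other lists, some of which share members with it, 1 was called too. The simulated genes varied independently of each other, while this list had an estimated correlation of 0.339 in the real arrays. The simulation therefore cannot show how the list tests do on correlated genes. Random sets and splits of arrays used fixed seeds. Figures were drawn with Matplotlib 3.10.9 and NumPy 2.4.6 under Python 3.11.15.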

Results

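Expression was measured on 15 arrays of magnetically sorted fetal liver cells from mid-gestation mouse embryos. TER119 selection takes up red cell precursors in their later stages, and the TER119 negative remainder holds earlier precursors and other cell types. The purity of the fractions is not known. The mean of the hepatocyte-lineage list was 11.03 in WT TER119 positive against 6.95 in WT TER119 negative arrays, so the positive fraction carried RNA of other cells too. There were 4 WT and 4 KO-labelled arrays of TER119 negative cells, and 4 WT and 3 KO-labelled arrays of TER119 positive cells. Correlations between arrays of a group lay between 0.992 and 0.995 in KO-labelled TER119 positive, 0.987 and 0.994 in WT TER119 positive, 0.982 and 0.995 in KO-labelled TER119 negative and 0.971 and 0.990 in WT TER119 negative cells. The first principal component of all arrays, which separated the populations, held 84.6% of the variance. Within TER119 negative cells the first component held 54.2%, and WT replicates 2 and 4 and KO replicate 4 stood apart on it. Xist and the Y-linked genes Eif2s3y, Kdm5d and Uty gave 4 male and 0 female arrays in WT TER119 negative cells against 1 male and 3 female arrays in KO-labelled TER119 negative cells. In TER119 positive cells they gave 2 male and 2 female WT arrays, and 1 male and 2 female KO-labelled arrays.

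Klf3 encodes a zinc finger protein that binds CACCC boxes and represses transcription, and it is itself switched on by the erythroid activator KLF1. Its probe set did not separate the genotypes. In TER119 positive cells Klf3 stood at 10.55, 10.34 and 10.52 in the KO-labelled arrays and at 10.37, 9.94, 10.50 and 10.08 in the WT arrays. The difference was 0.24 (SE 0.20, adjusted p = 1). Among TER119 negative cells, Klf3 stood at 8.02, 8.49, 8.74 and 8.09 in the KO-labelled arrays and at 8.80, 8.22, 8.55 and 7.94 in the WT arrays. That difference was -0.04 (SE 0.19, adjusted p = 0.947). The labels do not say which part of the gene was deleted, and a probe set outside that part checks nothing, so the genotype rests on the labels and the arrays are called KO-labelled throughout.

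The first comparison asked which genes differ between KO-labelled and WT cells among TER119 positive cells. The genes reported to be repressed by KLF3 rose. Klf8 encodes a related repressor that KLF3 holds down, Lgals3 encodes the carbohydrate-binding protein galectin-3, and C1qtnf12 encodes a secreted metabolic hormone. Rragd encodes a GTPase that passes amino acid signals to the mTORC1 kinase. Klf8 stood at 7.78 ± 0.13 (SD, n = 3) in KO-labelled and 4.71 ± 0.05 (n = 4) in WT cells, a difference of 3.06 (SE 0.12, adjusted p = 1.64e-10). Lgals3 rose by 2.94 (SE 0.15, adjusted p = 3.36e-09), from 7.58 to 10.52. C1qtnf12 rose by 3.34 (SE 0.13, adjusted p = 1.14e-10), from 5.62 to 8.96. Rragd rose by 4.77 (SE 0.15, adjusted p = 1.66e-11), from 4.68 ± 0.11 (SD, n = 4) to 9.45 ± 0.05 (n = 3). All 3 members of the KLF3-repressed list were measured and rose.

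**Figure D1:**
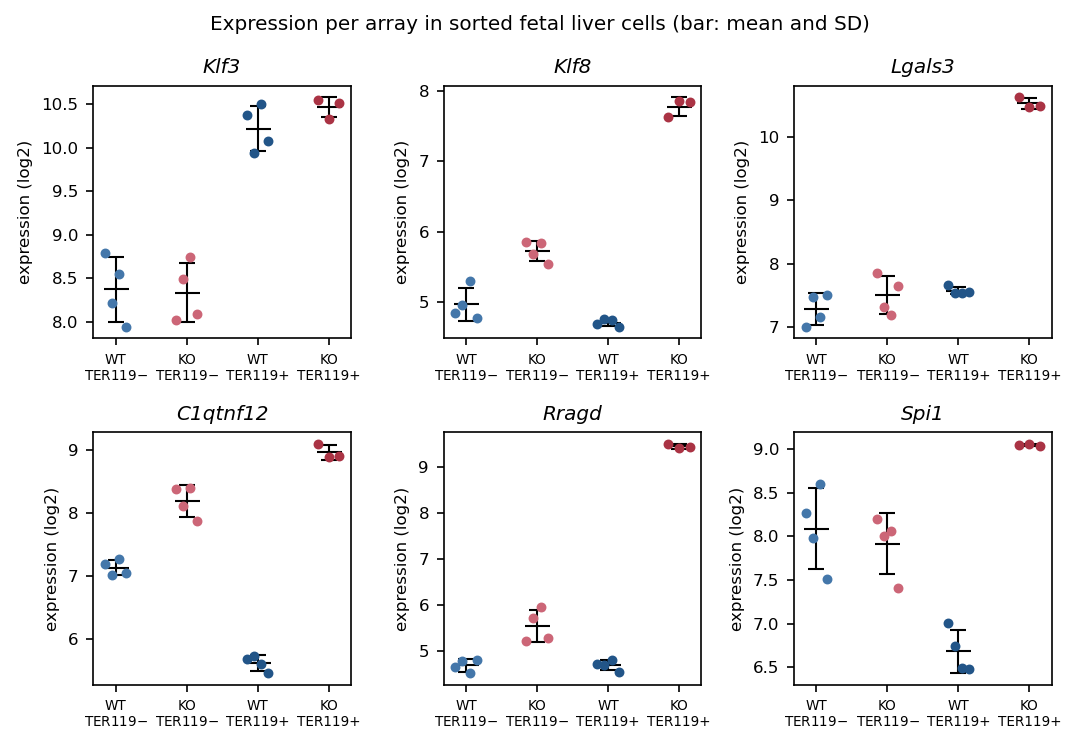
Log2 expression of named genes on each array, with points for single arrays of each group, bars at the group means and error bars of 1 SD. Klf8 has means of 7.78 in KO-labelled and 4.71 in WT TER119 positive cells, while Klf3 does not separate the genotypes.

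Other large rises in TER119 positive cells were in Pqlc3, which encodes a membrane transporter of the PQ-loop family, and in Kdelr3, which encodes a receptor that returns proteins to the endoplasmic reticulum. Supt3 encodes a subunit of a histone acetylating complex, Cttnbp2nl a cytoskeletal adaptor, Hydin a protein of cilia, and Dffb the nuclease that cleaves DNA in apoptosis. Pqlc3 rose by 4.09 (SE 0.15, adjusted p = 6.79e-11), Kdelr3 by 3.18 (SE 0.17, adjusted p = 6.8e-09) and Supt3 by 2.84 (SE 0.14, adjusted p = 2.03e-09). The rises of Cttnbp2nl, Hydin and Dffb were 2.69, 2.53 and 2.47. The deposited values hold no detection calls, so whether the low WT levels of Klf8, Rragd, Kdelr3 (4.25) and Hydin (4.51) lay above background is unknown, and the differences printed for these genes are not exact. Spi1, whose product PU.1 drives myeloid fates and opposes GATA1, rose by 2.36 (SE 0.22, adjusted p = 5.85e-06), to 9.04 ± 0.01 (SD, n = 3) from 6.68 ± 0.25 (n = 4). Fewer genes fell. Hsd3b6, a steroid dehydrogenase gene, fell by 2.14 (SE 0.23, adjusted p = 3.24e-05). Cd209f, which encodes a lectin of myeloid cells, fell by 1.58, Septin1, which encodes a filament-forming GTPase, by 1.47, and Grap2, which encodes an adaptor of T cell and platelet signalling, by 1.31. Vsig4, a complement receptor gene of tissue macrophages, fell by 1.21 (adjusted p = 0.000491), and Cbfa2t3, which encodes a corepressor in erythroid GATA1 complexes, fell by 1.06 (adjusted p = 0.0164). The KO levels of Cd209f (4.13) and Vsig4 (4.35) were similarly low, so the sizes of their falls are not exact either. Whether these 2 genes fell in red cell precursors or in other cells of the fraction was not tested. Amot, Ppm1e, Dapk2 and Ccdc189 completed the 10 largest falls and lay between -0.92 and -0.75.

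In TER119 positive cells 203 of 19938 genes passed the threshold, with 180 higher and 23 lower in KO-labelled cells, and 180 of them differed at least 1.5-fold (163 higher and 17 lower). At an unadjusted p under 0.05 there were 1062 genes, against 996.9 given by chance. The arrays of the groups did not overlap for 203 of the 203 genes past the threshold and for 2014 of all genes, where chance gives 5.71%.

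The erythroid groups in TER119 positive cells moved little. Of the 34 measured genes reported to be activated by KLF1, 1 rose, which was Klf8, also when adjusted over the list alone, and 33 did not pass; the list test was called (median 0.05, adjusted p = 0.0127; p = 0.394 with an estimated correlation). E2f2, which drives the last divisions of red cell precursors, and Aqp1, the water channel of the red cell, did not pass. Among 28 red cell membrane genes 1 rose, the complement inhibitor gene Cd59a (1.37, SE 0.23, adjusted p = 0.00414), and 1 rose and 1 fell when adjusted over the list alone (median 0.06, adjusted p = 0.108). Among 29 erythroid transcription regulators Spi1 rose, Cbfa2t3 fell and 27 did not pass, with 3 rising and 1 falling when adjusted over the list alone; the list's median was -0.07, its mean 0.05 and its test pointed up (adjusted p = 0.836). None of the 29 haem genes passed over all genes or adjusted over the list alone (median 0.03, adjusted p = 0.0955). The 6 measured globins (median 0.19, adjusted p = 0.102) and the 29 late erythroid genes (median -0.06, adjusted p = 0.313) held 0 calls either way. The largest globin difference was 1.27 for the embryonic Hba-x (SE 0.45, adjusted p = 0.476). In the KLF and SP family of 25 genes Klf8 alone passed, with 1 rising and 1 falling when adjusted over the list alone; the family's median was -0.04 and its mean 0.11 (adjusted p = 0.522).

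Among groups of general cell functions in TER119 positive cells, the 40 cell cycle genes held 0 calls over all genes or adjusted over the list alone, while the list test was called up (median 0.07, adjusted p = 0.0486; p = 0.521 with an estimated correlation). The 36 ribosomal protein genes also held 0 calls (median 0.05, adjusted p = 0.0522). Of 22 interferon response genes the antiviral gene Rsad2 rose by 1.12 (SE 0.16, adjusted p = 0.000593), the only member also when adjusted over the list alone (median 0.05, adjusted p = 0.0813). Among 18 p53 target genes 0 passed and 1 fell when adjusted over the list alone (median 0.03, mean -0.01, test up, adjusted p = 0.836).

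Markers of other cell types were measured in the same TER119 positive arrays. The 17 megakaryocyte and platelet markers were lower as a group (median -0.77, adjusted p = 1.39e-10; p = 0.0898 with an estimated correlation), though 0 passed over all genes or adjusted over the list alone. Members with the smallest p were Treml1 (-0.73), F2rl2 (-0.78) and Thbs1 (-0.80), which serve platelet activation. The 18 stromal and stellate markers were higher as a group (median 0.23, adjusted p = 0.00187; p = 0.247 with an estimated correlation), as were the 22 neutrophil and granulocyte precursor markers (median 0.13, adjusted p = 0.0486; p = 0.433 with an estimated correlation), each with 0 calls either way. The stromal and hepatocyte-lineage means per array were both lowest in KO replicate 3 and WT replicates 1 and 3. Vsig4 fell among the 26 macrophage markers and 2 fell when adjusted over the list alone; the median was 0.01, the mean -0.07 and the test pointed down (adjusted p = 0.248). The 27 hepatocyte-lineage markers (median 0.10, adjusted p = 0.218) and the 23 progenitor markers (median -0.06, adjusted p = 0.252) held 0 calls, as did the 17 B cell (median -0.06, adjusted p = 0.315), 14 mast cell (median -0.03, adjusted p = 0.799) and 15 T and natural killer cell markers (median -0.03, adjusted p = 0.358). In the 18 endothelial markers the median was 0.02 and the mean slightly below 0, the test pointed up (adjusted p = 0.836), and 0 passed. Of the 4 measured sex-linked genes 0 passed in either KO comparison.

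The second comparison asked the same of TER119 negative cells. Sidt2, which encodes a lysosomal membrane protein that carries nucleic acids, and Apol8, an apolipoprotein L family gene, rose most. Bcl2l15 encodes a member of the BCL2 family of apoptosis regulators and Serpinb6a an intracellular protease inhibitor. Of the genes reported to be repressed by KLF3, C1qtnf12 and Klf8 rose here as well. Sidt2 rose by 2.27 (SE 0.23, adjusted p = 0.000154) and Apol8 by 1.96 (SE 0.18, adjusted p = 5.69e-05). Bcl2l15 stood at 7.18 ± 0.17 (SD, n = 4) in KO-labelled and 5.47 ± 0.13 (n = 4) in WT cells (adjusted p = 2.4e-06), and Serpinb6a rose by 1.62 (SE 0.14, adjusted p = 4.57e-05). C1qtnf12 rose by 1.06 (SE 0.12, adjusted p = 0.000488), Rragd by 0.86 (SE 0.14, adjusted p = 0.0236) and Klf8 by 0.75 (SE 0.11, adjusted p = 0.0148). Lgals3 did not pass (0.22, SE 0.14, adjusted p = 0.682), so 2 of the 3 KLF3-repressed genes rose over all genes. Plek2, an actin regulator of late red cell precursors, rose by 1.08, and Arl15, Mgst3 and Acp5 by 0.98, 0.89 and 0.87. Tmem45a2 fell by 0.52 (adjusted p = 0.0377) and Mir532 fell by 0.46 (adjusted p = 0.0475). Of the 4 KO-labelled values of Mir532, 3 were identical at 4.42.

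There were 17 genes past the threshold in TER119 negative cells, 15 higher and 2 lower in KO-labelled cells, and 15 differed at least 1.5-fold, all of them higher. At an unadjusted p under 0.05 there were 1508 genes against 996.9 given by chance. The arrays of the groups did not overlap for 17 of the 17 genes past the threshold and for 524 of all genes, where chance gives 2.86%. Sex was unevenly spread here. A sex factor leaves the 1 male KO-labelled array to be set against the male WT arrays. With sex as a factor 1 of the 17 genes, Bcl2l15, remained past the threshold. The median difference of the 15 higher genes was 0.97 (median SE 0.20) against 0.89 (median SE 0.12) without it. Most of the 15 shrank with this factor, such as Crip1 (0.81 to 0.61), while others rose, such as Rragd (0.86 to 1.03).

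Of the erythroid groups in TER119 negative cells, the KLF1-activated, red cell membrane, haem and regulator lists were called higher, while globin and late erythroid genes were not called; several groups of other cell types were lower. Of 34 genes reported to be activated by KLF1, 1 rose over all genes and 9 when adjusted over the list alone (median 0.27, adjusted p = 1.46e-11; p = 0.0456 with an estimated correlation). Red cell membrane genes were higher as a group (median 0.30, adjusted p = 4.48e-08; p = 0.0641 with an estimated correlation), with 0 of 28 passing over all genes and 6 rising when adjusted over the list alone. Tmod1, which caps actin filaments in the membrane skeleton, differed by 0.92 (adjusted p = 0.0584). Haem genes were higher (median 0.20, adjusted p = 8.25e-07; p = 0.143 with an estimated correlation), with 0 of 29 passing over all genes and 2 when adjusted over the list alone. Erythroid transcription regulators (median 0.13, adjusted p = 0.00187; p = 0.312 with an estimated correlation) and cell cycle genes (median 0.12, adjusted p = 0.000502; p = 0.278 with an estimated correlation) were higher with 0 calls either way. So were ribosomal protein genes (median 0.04, adjusted p = 0.0159; p = 0.303 with an estimated correlation). Beside these groups, the hepatocyte-lineage markers were lower on the same arrays (median -0.77, adjusted p = 4.44e-09; p = 0.145 with an estimated correlation), with 0 of 27 passing either way. Their mean per array was 6.27 ± 0.59 (SD, n = 4) in KO-labelled and 6.95 ± 0.82 (n = 4) in WT cells, and the 3 arrays that stood apart lay between 6.89 and 7.81, but WT replicate 3, which did not stand apart, lay at 7.26. Without those 3 arrays, a setting chosen after seeing the data, the medians were 0.091 for KLF1-activated, 0.092 for red cell membrane, 0.024 for haem and -0.026 for regulator genes, while the hepatocyte median was -0.57. Cell cycle genes turned to a median of -0.020 without these arrays and -0.045 with the hepatocyte-list covariate, a setting also chosen afterwards. Haem, regulator and cell cycle genes were called under neither setting.

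Neutrophil and granulocyte precursor markers were lower in KO-labelled TER119 negative cells (median -0.30, adjusted p = 2.45e-06; p = 0.0921 with an estimated correlation), with 0 of 22 passing over all genes and 1 falling when adjusted over the list alone. Chil3, a gene of neutrophil granules, differed by -0.85 (adjusted p = 0.0583). T and natural killer cell markers were lower (median -0.21, adjusted p = 0.000483; p = 0.0234 with an estimated correlation), as were B cell markers (median -0.11, adjusted p = 0.0122; p = 0.128 with an estimated correlation), each with 1 falling when adjusted over the list alone. Mast cell markers were lower with 0 calls either way (median -0.16, adjusted p = 0.0375; p = 0.0553 with an estimated correlation). Megakaryocyte markers were called lower too, with 0 calls of members either way (median -0.25, adjusted p = 0.0211; p = 0.491 with an estimated correlation), but their direction was not kept. Without KO replicate 3 the median of megakaryocyte markers was -0.013 and their test pointed up. With the hepatocyte-list covariate their median was 0.23, while that of T and natural killer cell markers was -0.092. Mast cell and B cell markers were not called with that covariate, while neutrophil and T and natural killer cell markers were. In the KLF and SP family 1 gene rose over all genes and 3 when adjusted over the list alone (median -0.08, adjusted p = 0.836). The remaining lists were not called and held 0 calls over all genes or adjusted over the list alone. They were globins (median -0.38, adjusted p = 0.136), late erythroid (0.05, 0.0992), p53 target (0.04, 0.771), interferon (-0.04, 0.653), progenitor (-0.13, 0.292), macrophage (-0.05, 0.245), endothelial (-0.10, 0.187) and stromal markers (-0.12, 0.311), with the median and adjusted p of each in this order.

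**Figure D2:**
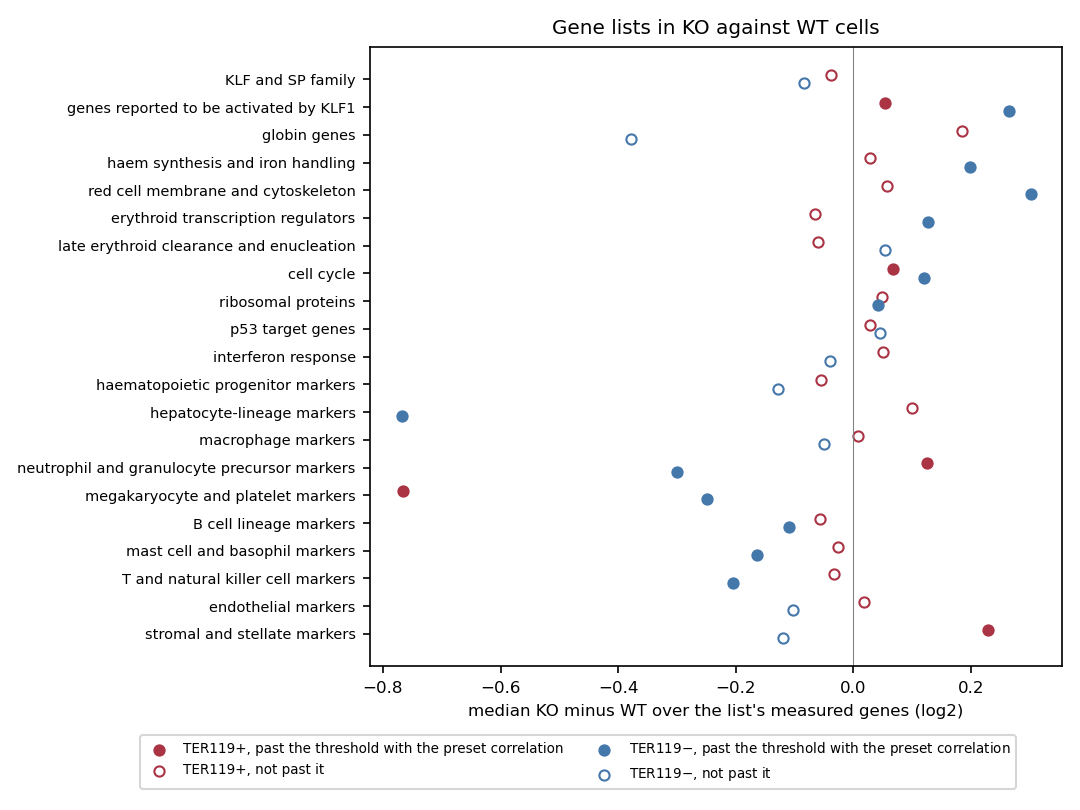
Median log2 difference between KO-labelled and WT cells for each gene list, in TER119 positive and TER119 negative cells. The hepatocyte-lineage list lies at -0.77 in TER119 negative and at 0.10 in TER119 positive cells.

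**Figure D3:**
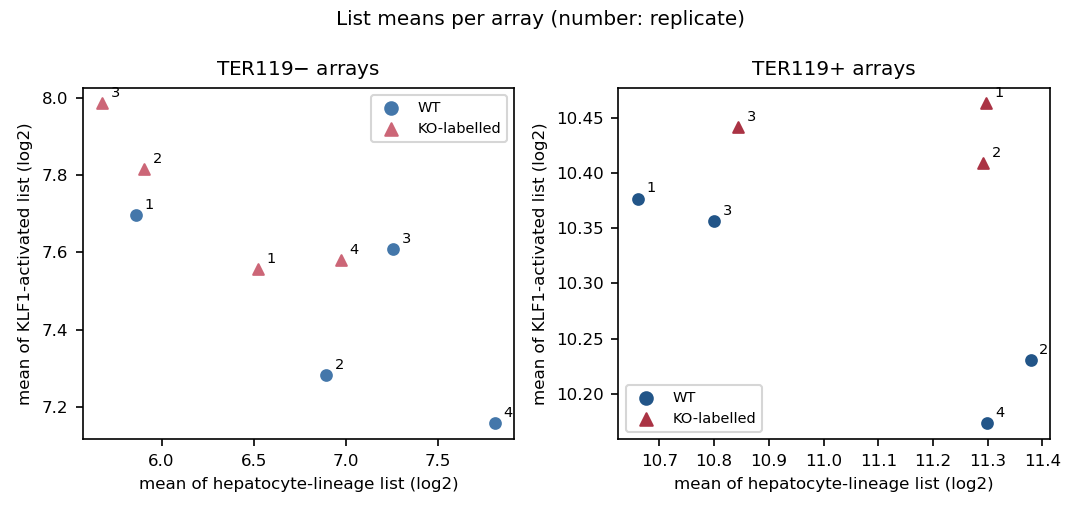
Mean log2 expression of the KLF1-activated list (vertical axis) against that of the hepatocyte-lineage list (horizontal axis), a point per array, in each population. The hepatocyte-lineage list lies between 5.68 and 6.97 in KO-labelled and between 5.86 and 7.81 in WT TER119 negative arrays.

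Whether the populations differed in their response was tested as the difference between the KO effects. Rragd, Pqlc3, Kdelr3, Supt3 and Lgals3 rose more in TER119 positive cells, and Klf8 and C1qtnf12, although higher in both populations, rose more there too. The difference between the effects was 3.90 for Rragd (SE 0.20, adjusted p = 4.48e-08), 3.51 for Pqlc3 (SE 0.20, adjusted p = 5.7e-08) and 2.73 for Lgals3 (SE 0.21, adjusted p = 1.03e-06). It was 2.31 for Klf8 and 2.29 for C1qtnf12. In the other direction stood Bcl2l15 (-1.74, SE 0.17, adjusted p = 3.43e-05), which in TER119 positive cells differed by -0.03. Septin1 (-1.61), Hsd3b6 (-1.57), Cd209f (-1.48) and Serpinb6a (-1.03) followed. In all 87 genes passed, 74 more positive and 13 more negative in TER119 positive cells, and all 87 by at least 1.5-fold; 852 genes had an unadjusted p under 0.05 against 996.9 given by chance. The count was 56 above the 50th percentile of expression and 38 with sex, unevenly spread in TER119 negative cells, as a factor, a setting chosen after seeing the data.

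Between the populations 11 list tests differed in their KO effect. More positive in TER119 positive cells were globin genes (median 0.55, adjusted p = 0.0189; p = 0.106 with an estimated correlation), hepatocyte-lineage markers (0.83, adjusted p = 1.32e-08; p = 0.157 with an estimated correlation), neutrophil markers (0.44, adjusted p = 4.48e-08; p = 0.0579 with an estimated correlation), stromal markers (0.30, adjusted p = 0.00132; p = 0.23 with an estimated correlation) and T and natural killer cell markers (0.12, adjusted p = 0.0472; p = 0.154 with an estimated correlation). More negative were KLF1-activated genes (-0.25, adjusted p = 0.00526; p = 0.345 with an estimated correlation), haem genes (-0.11, adjusted p = 0.0127; p = 0.42 with an estimated correlation) and red cell membrane genes (-0.24, adjusted p = 0.00288; p = 0.268 with an estimated correlation). Erythroid regulators (-0.21, adjusted p = 0.0311; p = 0.472 with an estimated correlation), late erythroid genes (-0.12, adjusted p = 0.0311; p = 0.375 with an estimated correlation) and megakaryocyte markers (-0.47, adjusted p = 0.00143; p = 0.351 with an estimated correlation) were also more negative. These calls depended on the hepatocyte list and on the 3 arrays that stood apart, in settings chosen after seeing the data. With the hepatocyte-list covariate 4 lists were called, and the tests of KLF1-activated (-0.038), haem (0.046) and regulator genes (0.025) reversed. Without the 3 arrays 7 were called, and those of haem (0.016), regulator (-0.025) and late erythroid genes (0.035) reversed. The KLF1-activated, haem, red cell membrane, regulator and late erythroid lists were called under neither. Klf8 passed among the KLF1-activated genes, Spi1 among the erythroid regulators and Rsad2 among the interferon genes. For ribosomal protein genes the median was 0.00 while mean and test were below 0, and for progenitor and macrophage markers the median was above 0 while mean and test were below, none of them called.

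The genes shared by both populations were few and went the same way. Acp5, Apol8, Arl15, C1qtnf12, Crip1, Klf8, Mgst3, Rragd and Sidt2 were higher in KO-labelled cells of both. These 9 genes compare with 0.135 given by chance (Fisher's exact test, 2-sided, p = 1.56e-15). The test takes the calls of the comparisons as independent, though they share the estimated spread of each gene, so this p-value is not exact. The shared count was 3 on only the arrays compared, 4 with the Y-linked covariate and 0 with sex as a factor. It was 5 without KO TER119 negative replicate 3 or without WT TER119 negative replicate 1 or 2. With sex as a factor the differences of the 9 genes in TER119 negative cells ran from 0.61 for Crip1 (0.81 without it) to 2.37 for Sidt2 (2.27 without it). Errors were wider there, with an SE of 0.23 against 0.14 for Crip1 and 0.39 against 0.23 for Sidt2. These differences rest on the 1 male KO-labelled TER119 negative array. No gene was lower in both and 0 went in opposite directions. Across genes, which are not independent replicates, the differences correlated with a Pearson coefficient of 0.248 and a Spearman coefficient of 0.217.

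**Figure D4:**
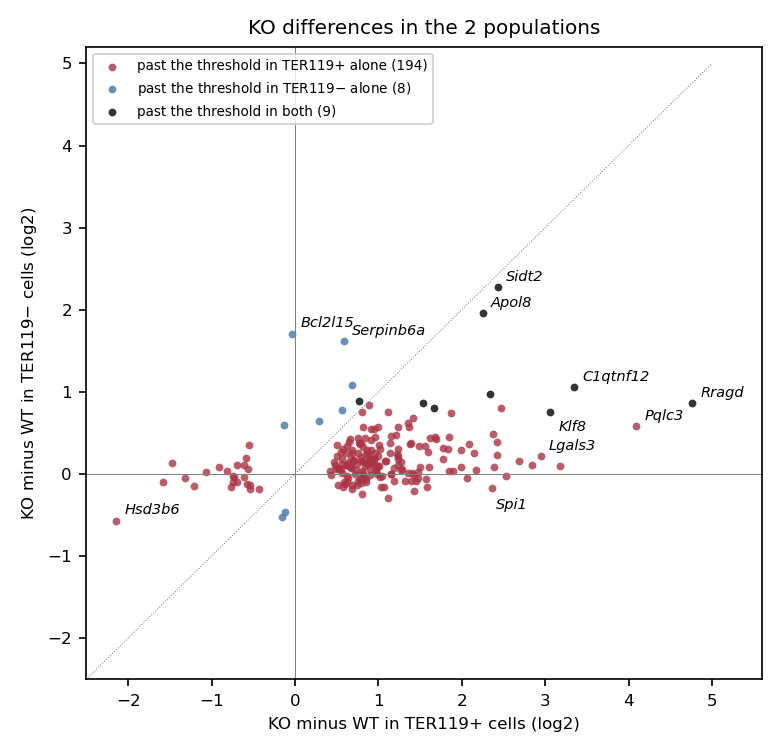
Log2 difference between KO-labelled and WT cells in TER119 negative against TER119 positive cells, with a point per gene. The 9 genes higher in both include Rragd at 4.77 in TER119 positive and 0.86 in TER119 negative cells.

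A further comparison asked whether the KO labels shift the genes that mark either population. The 200 genes highest in TER119 positive cells were higher in KO-labelled TER119 positive cells (median 0.10, camera p = 0.00126; p = 0.281 with an estimated correlation). With 1 array left out this median lay between 0.018 and 0.21, and the call was lost without KO replicate 1 or 2 or WT replicate 1 of that population, above the 50th percentile of expression and with the hepatocyte-list covariate (0.021). The 200 genes highest in TER119 negative cells had a median of 0.01 there (camera p = 0.0771; p = 0.573 with an estimated correlation). In TER119 negative cells the medians of these sets were -0.11 (camera p = 0.359; p = 0.753 with an estimated correlation) and -0.04 (camera p = 0.307; p = 0.743 with an estimated correlation). These p-values are not adjusted.

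The last comparison set TER119 positive against TER119 negative WT cells. Genes of late red cell precursors were higher in TER119 positive cells, among them Alas2, which makes the first product of haem synthesis, and Slc4a1, which encodes the main anion exchanger of the red cell membrane. Genes of neutrophil precursors, such as S100a8 and S100a9, were lower. Hepatocyte genes were also higher in the TER119 positive fraction. The labels name no batch, and whether a batch between the populations added to the differences was not tested. Alas2 was higher by 5.77 (SE 0.16, adjusted p = 6.52e-14) and Slc4a1 by 5.33 (adjusted p = 3.12e-13). S100a9 fell by 6.76 (SE 0.20, adjusted p = 1.12e-13) and S100a8 fell by 6.41. The largest rises were in the hepatocyte genes Ahsg (6.22, SE 0.38) and Serpinf2 (6.12, SE 0.24) and the macrophage gene Cd5l (6.12, SE 0.14), and Tent5c and Ypel4 were among the 10 largest. Klf3 was higher by 1.85 (SE 0.19, adjusted p = 3.53e-07) and Klf1 by 1.84. C1qtnf12 was lower (-1.51, adjusted p = 1.33e-08), and Klf8 (-0.26, adjusted p = 0.0677) and Lgals3 (0.29, adjusted p = 0.0961) did not pass. In all 10486 genes passed, 4693 higher and 5793 lower; of these 6925 differed at least 1.5-fold (3506 higher and 3419 lower). Arrays did not overlap for 8829 genes past the threshold and for 9100 of all genes, where chance gives 2.86%.

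Most members of the erythroid lists were higher in WT TER119 positive cells. Of the KLF1-activated genes 31 of 34 rose and 1 fell (median 2.65, adjusted p = 9.28e-20; p = 0.0113 with an estimated correlation), with 31 and 2 when adjusted over the list alone. Of the haem genes 25 rose and 3 fell of 29 (2.00, adjusted p = 1.54e-14; p = 0.0343 with an estimated correlation), and of the red cell membrane genes 25 rose and 1 fell of 28 (2.48, adjusted p = 2.59e-14; p = 0.0168 with an estimated correlation). Late erythroid genes rose in 26 and fell in 2 of 29 (2.17, adjusted p = 1.06e-16; p = 0.00679 with an estimated correlation), and globins rose in 4 of 6 (1.58, adjusted p = 0.00742; p = 0.0707 with an estimated correlation). Erythroid regulators rose in 18 and fell in 8 of 29 (1.39, adjusted p = 0.000226; p = 0.238 with an estimated correlation), with 20 and 8 when adjusted over the list alone. Cell cycle genes rose in 25 and fell in 5 of 40 (0.83, adjusted p = 1.32e-05; p = 0.189 with an estimated correlation), while ribosomal protein genes rose in 4 and fell in 24 of 36 (median -0.45, adjusted p = 0.000494; p = 0.152 with an estimated correlation).

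Of the lists of other cell types, hepatocyte markers rose in 26 of 27 (median 4.29, adjusted p = 4.93e-15; p = 0.0622 with an estimated correlation) and macrophage markers in 18 of 26, with 4 falling (1.32, adjusted p = 4.48e-08; p = 0.01 with an estimated correlation). Endothelial markers rose in 15 of 18 (1.15, adjusted p = 1.64e-05; p = 0.149 with an estimated correlation) and stromal markers in 12 of 18 (1.13, adjusted p = 0.0018; p = 0.243 with an estimated correlation). Neutrophil markers fell in 21 of 22 and rose in 1 (median -4.90, adjusted p = 1.65e-14; p = 0.0136 with an estimated correlation), and progenitor markers fell in 16 and rose in 2 of 23 (-0.83, adjusted p = 0.00188; p = 0.119 with an estimated correlation). Mast cell markers fell in 10 and rose in 2 of 14 (-0.67, adjusted p = 0.00188; p = 0.00976 with an estimated correlation), B cell markers fell in 7 of 17 (-0.27, adjusted p = 0.0305; p = 0.182 with an estimated correlation) and T and natural killer cell markers in 7 of 15 (-0.28, adjusted p = 0.0149; p = 0.0897 with an estimated correlation). The lists of the KLF and SP family (12 higher, 5 lower of 25, adjusted p = 0.0731), p53 target genes (7 and 6 of 18, adjusted p = 0.376), interferon response (6 and 9 of 22, median -0.12, mean 0.14, test up, adjusted p = 0.958) and megakaryocyte markers (3 and 4 of 17, median -0.24, mean 0.02, test up, adjusted p = 0.972) were not called. Counts adjusted over the list alone were the same for the lists in WT cells, except for the KLF1-activated genes and erythroid regulators given with their lists, the KLF and SP family (13 and 6), p53 targets (8 and 6), macrophages (20 and 4) and ribosomal proteins (4 and 25). Of the sex-linked genes Kdm5d fell by 2.15 (adjusted p = 0.018), in a comparison where WT TER119 negative arrays were all male.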

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

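The counts over other splits of the arrays, including those for genes and for lists, were planned before the results were seen; the tests of sex, hepatocyte RNA, dilution and neighbouring genes were chosen after the result was seen. In 17 of 597 groups of 4 arrays (178 genes and 21 list means) a single array stood far from the others, where chance flags about 1 in 20 groups, or 29.85 here. The values are the gap to the nearest array divided by the range. In WT TER119 negative replicate 4 they were 0.968 for Pqlc3, 0.879 for Rpl14, 0.879 for Mecom and 0.893 for Hhex. In KO-labelled TER119 negative replicate 4 they were 0.873 for Phlda3, 0.896 for Zmat3, 0.934 for Mecom and 0.873 for Sqstm1. In WT TER119 negative cells Slc40a1 (0.89) stood apart in replicate 1, and Prss34 (0.838) and Hmox1 (0.843) in replicate 3. In KO-labelled TER119 negative cells Mir532 (1) stood apart in replicate 2, where the other arrays were identical, and the mean of the neutrophil list (0.908) in replicate 1. In WT TER119 positive cells Irf7 (0.912) stood apart in replicate 1, Cd209f (0.93) and Mycn (0.876) in replicate 2 and Ebf1 (0.918) in replicate 3.

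The KO difference itself differed between the populations, by the interaction test, in 20 named genes. More positive in TER119 positive cells were Rragd (3.90), Pqlc3 (3.51), Kdelr3 (3.08), Supt3 (2.73), Lgals3 (2.73), Hydin (2.55), Cttnbp2nl (2.54), Spi1 (2.53), Klf8 (2.31), C1qtnf12 (2.29), Dffb (1.67), Rsad2 (1.41) and Arl15 (1.36). More negative were Bcl2l15 (-1.74), Septin1 (-1.61), Hsd3b6 (-1.57), Cd209f (-1.48), Serpinb6a (-1.03), Amot (-1) and Ccdc189 (-0.64). List medians differed for KLF1-activated genes (-0.25), globins (0.55), haem (-0.11), red cell membrane (-0.24), erythroid regulators (-0.21), late erythroid genes (-0.12), hepatocyte (0.83), neutrophil (0.44), megakaryocyte (-0.47), T and natural killer cell (0.12) and stromal markers (0.30). Among the 13610 probe sets with no symbol or several, which no comparison of genes used, 29 passed between KO-labelled and WT TER119 positive cells (27 higher and 2 lower, from 2.59 to -1.30) and 1 between KO-labelled and WT TER119 negative cells (1.46).

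Other splits of the arrays tested whether chance can be excluded. For genes in TER119 positive cells 2 of 35 splits gave at least the 203 real genes, and the highest other gave 525, while every further split gave at most 1, so this count alone did not exclude chance. That split set KO replicate 3 and WT replicates 1 and 3 against the rest, which points to a structure of the samples and makes it a poor measure of chance. These 3 arrays had the lowest means of the hepatocyte list (10.66 to 10.84, against 11.29 to 11.38) and of the stromal list (5.72 to 6.16, against 6.41 to 6.69) among TER119 positive arrays. In TER119 negative cells 6 of 35 splits gave at least 17 genes, the highest other 3563, and chance was not excluded. That split set KO replicates 1 and 4 and WT replicates 2 and 4 against the rest, and it too points to a structure of the samples. For the interaction 7 of 100 splits gave at least 87 genes, the highest other 2002, which again points to such a structure, and chance was not excluded. For the WT populations 1 of 35 splits, the real one, gave 10486 genes and the highest other 0. Every other split mixed the populations in both of its groups, which widens the estimated spread of genes that differ between them. Such splits could hardly call these genes, so they are a poor measure of chance, and no conclusion is drawn from this count. The 9 genes higher in both populations were reached by 1 of 100 splits, the real one, with 5 as the highest other, so chance was excluded for the fit without covariates. With sex as a factor there were 0 such genes. In TER119 negative cells their differences under that factor ran from 0.61 (Crip1) to 2.37 (Sidt2), with wider errors. These differences set the 1 male KO-labelled array against the male WT arrays. Arrays of the genes called there did not overlap between groups, so that array already lay above the WT arrays. The sign of these differences is therefore no further evidence. For list tests chance was not excluded: 26 of 35 splits gave at least 5 lists in TER119 positive cells (highest other 12), 6 of 35 at least 12 in TER119 negative cells (highest other 14), 21 of 100 at least 11 for the interaction (highest other 15) and 4 of 35 at least 17 for the WT populations (highest other 17). The other splits that reached 17 each held 3 arrays of 1 population against 3 of the other, so they carried much of the population difference and are a poor measure of chance. The larger median of the population sets was reached by 19 of 35 splits in TER119 positive cells (0.10, highest other 0.23) and by 11 of 35 in TER119 negative cells (0.11, highest other 0.23), so chance was not excluded.

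The first pattern is the set of 15 genes, such as Sidt2, Apol8 and Bcl2l15, that were higher in KO-labelled TER119 negative arrays, where sex and hepatocyte RNA differed too. With the Y-linked covariate their median went from 0.89 to 0.98 (median SE 0.12 before and 0.16 after). Most of the single genes shrank, however, such as Crip1 (0.81 to 0.71), while others rose, such as Rragd (0.86 to 0.98). With the hepatocyte-list covariate the median was 0.83 (SE 0.13). All 15 stayed above 0 under both, and the lowest 95% bounds were 0.26 and 0.32, which argues against either as the whole cause. Of the 17 calls 6 and 9 remained, and with sex as a factor (median 0.97, SE 0.20) 1 remained. The errors of the calls that ended had widened under each setting, and most of their differences had also shrunk. Examples are Arl15 with the hepatocyte list (0.98 to 0.83, SE 0.17 to 0.18) and Crip1 with sex as a factor (0.81 to 0.61, SE 0.14 to 0.23). Between female and male TER119 positive arrays the 15 genes differed by a median of 0.04 (from -0.20 to 0.15). The genotype stays open as a hypothesis.

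Erythroid lists on the same arrays went from a median of 0.23 over 4 lists to 0.043 with the hepatocyte-list covariate (lowest p = 0.221 with an estimated correlation), so a differing share of hepatocyte RNA may account for part of them. Without the 3 arrays that stood apart, however, the KLF1-activated list fell to 0.091, red cell membrane to 0.092, haem to 0.024 and regulators to -0.026, while the hepatocyte list stayed at -0.57, so another property of those arrays stays open too. The most abundant hepatocyte genes were lower in KO-labelled than WT TER119 negative cells: Alb at 9.26 ± 0.88 against 10.31 ± 1.16, Serpina6 at 9.33 against 10.19, Afp at 8.47 against 9.34 and Trf at 8.17 against 8.93 (n = 4 each, none passing). The sort could move hepatocyte RNA too, since Alb stood at 13.61 in WT TER119 positive cells, and 0 of the 27 list genes are in another list. Hepatocyte and KLF1-activated lists were both higher in WT TER119 positive cells (medians 4.29 and 2.65). In KO-labelled TER119 negative cells, however, the first was lower (-0.77) and the second higher (0.27). An effect of the sort was not tested. The neutrophil list went from -0.30 to -0.27 with this covariate, so the hepatocyte share took away little of it. With an estimated correlation it passed neither before (p = 0.0921) nor after (p = 0.153), and this spread leaves its cause open.

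The second pattern is that most of the 180 genes called higher in TER119 positive cells rose less, on the linear scale, in TER119 negative cells. These genes were chosen by their difference in TER119 positive cells, which by itself favours smaller values in the other population. If the TER119 negative arrays held a fixed share of the same responding cells, the linear-scale increase of every gene would shrink by a common factor. The group means were therefore turned back from log2, and the shares are shares of linear increases, not of the log2 differences printed elsewhere. At the best share of 5.9%, found among 1501 tried, 21 of the 180 higher genes departed (11.7%, against a limit of 5%), 14 above it, such as Mgst3, Sidt2 and C1qtnf12, and 7 below it, such as Rsad2 and Cttnbp2nl. Bcl2l15 and Serpinb6a differed more in TER119 negative cells. The 7 genes below the share lay between 4.29 (Shroom2) and 5.27 (Rsad2) in WT TER119 negative cells, where RMA compresses differences. Many of those above it were brighter, such as Mgst3 (8.39), though Slc52a3 (4.64) was not. Compression could thus add to the departures, and their count cannot decide against a single dilution. A dilution alone would not give Bcl2l15 and Serpinb6a their larger difference in TER119 negative cells. A response that depends on the stage of the cells stays open as an untested hypothesis.

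The third pattern is that called genes lay next to each other on a chromosome: in TER119 positive cells there were 12 neighbouring pairs, of which 8 were left without overlapping genes and names that share their first 4 letters, against a mean of 1.97 and a highest of 9 in 10000 random sets matched on expression and counted the same way (permutation p = 0.001). Without pairs of microRNA genes, of which Mir144 and Mir451a share a precursor, 7 were left (permutation p = 0.0041). The pairs were Mir144 and Mir451a, Unc13d and Wbp2, Rsad2 and Cmpk2, Plec and Parp10, Setd4 and Cbr1, Ehbp1l1 and Fam89b, Prune2 and Gcnt1, and Rragd and Ube2j1. Neighbouring genes may thus change together, though a cause such as shared regulatory DNA was not tested. DNA of another strain carried along with the deleted gene would put pairs around Klf3, but 0 pairs lay within 100 measured genes on either side, where 1 gene (Pi4k2b) was called against 2.04 given by chance.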

How the results depend on the processing

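The tests without the 3 TER119 negative arrays that stood apart, with the hepatocyte-list covariate and with sex as a factor were chosen only after the result was seen. For named genes, the side of the threshold, and the direction where either fit called the gene, were kept in most tests under an alternative. These were 2193 of 2240 tests in TER119 positive and 1996 of 2112 in TER119 negative cells. For the interaction they were 234 of 267, and for the WT populations 2142 of 2155. Genes called in neither fit counted as kept whatever their direction. Calls were lost in 19, 105, 33 and 4 of these tests, in the same order. Of the 13 named genes called in TER119 negative cells, 6 kept their call with the Y-linked covariate and 1 with the sex factor. In TER119 positive cells the 203 genes became 350 on only the arrays compared, 386 with array weights and 323 without the 3 arrays. In TER119 negative cells the 17 genes became 4 on only the arrays compared, 31 with array weights, 6 with the Y-linked covariate, 8 without the 3 arrays, 10 with the hepatocyte-list covariate and 1 with the sex factor. Their 1.5-fold count of 15 became 4, 24, 6, 8 and 1 under these, leaving out the hepatocyte list. The interaction's 87 genes, and its 1.5-fold count, became 56 above the 50th percentile and 38 with the sex factor. The 9 shared genes became 3 on only the arrays compared, 19 with weights, 4 with the Y-linked covariate and 0 with the sex factor. List calls in TER119 positive cells (5) became 2 and 3 above the 30th and 50th percentiles and 8 on only the arrays compared. In TER119 negative cells (12) they became 6 with the hepatocyte list, and for the interaction (11) 6 after quantile normalization, 7 without the 3 arrays and 4 with the hepatocyte list. The set highest in TER119 positive cells lost its call in TER119 positive cells above the 50th percentile (0.10) and with the hepatocyte list (0.021). The set highest in TER119 negative cells gained one there without the 3 arrays (0.026). In TER119 negative cells the first set gained a call above the 30th and 50th percentiles (-0.11) and without the 3 arrays (-0.10). The other gained one after quantile normalization (-0.11), above both percentiles (-0.035), without the 3 arrays (-0.10) and with the sex factor (-0.089). Reversed in TER119 negative cells with the hepatocyte list were erythroid regulators (-0.044), cell cycle (-0.045), megakaryocyte (0.23) and the hepatocyte list itself (0.035), the last by construction; the megakaryocyte test also reversed without KO replicate 3 (median -0.013, mean 0.020; medians from -0.53 to -0.013 over the arrays left out). For the interaction KLF1-activated (-0.038), haem (0.046), erythroid regulator (0.025) and hepatocyte (-0.040) lists reversed with the hepatocyte list, and haem (0.016), erythroid regulator (-0.025) and late erythroid lists (0.035) without the 3 arrays; where median and test differ in sign the test was used. Eif2s3y reversed between WT populations with the Y-linked covariate (0.39), which holds that gene. Unless stated, the cause was not tested.

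Leaving out each array in turn gave 148 to 226 genes in TER119 positive cells (1.5-fold 144 to 190), 8 to 24 in TER119 negative cells (8 to 23), 61 to 93 for the interaction (61 to 92) and 9647 to 10934 for the WT populations (6813 to 7063). The TER119 negative count moved over 1.5 times without KO TER119 positive replicate 1 (11) or 2 (11), KO TER119 negative replicate 2 (11) or 3 (8) and WT TER119 negative replicate 2 (8), and its 1.5-fold count also without WT TER119 negative replicate 3 (23). List calls ranged from 3 to 8, 9 to 14, 5 to 12 and 17 to 17. They moved over 1.5 times in TER119 positive cells without WT TER119 positive replicate 1 (8) or KO TER119 negative replicates 2 or 3 (3), and for the interaction without KO TER119 negative replicate 3 (6) or WT TER119 negative replicates 2 (7) or 4 (5). Shared genes ranged from 5 to 11, with 5 without KO TER119 negative replicate 3 or WT TER119 negative replicates 1 or 2. The medians of the population sets ranged from 0.018 to 0.21 and from -0.0075 to 0.049 in TER119 positive cells, and from -0.15 to -0.06 and from -0.11 to 0.0049 in TER119 negative cells. The first lost its call without KO TER119 positive replicates 1 (0.018) or 2 (0.044) or WT TER119 positive replicate 1 (0.018).

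With the replicate number as a block there were 171 genes in TER119 positive cells, 10 in TER119 negative cells, 66 for the interaction and 8737 for the WT populations. Same-numbered arrays deviated with correlations from -0.38 to 0.65, and not every array correlated best with its own number, a hint from the data that the numbers do not pair the arrays. Between the fractions, the sex read from the arrays differed for WT replicates 1 and 4 and for KO replicates 1 and 2. This argues against the same embryo behind those numbers in both fractions, while a pairing by litter stays open. The sex factor could not be fitted for the WT populations, since WT TER119 negative arrays were all male. Signal over background limits dim genes, whose differences RMA compresses.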

Other observations

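The genes in this paragraph were chosen after their values were seen, and no test was made of them as groups. Beyond the named genes, several genes of the cell surface and skeleton rose in KO-labelled TER119 positive cells. Cd55 (0.79) and Cd59b (1.19) encode inhibitors of complement on the red cell surface; Cd59b is a near copy of Cd59a, so that their values are not separate measurements. Lmna (0.95) encodes the nuclear lamina protein lamin A, and Sun1 (1.41) and Syne3 (0.65) encode proteins that tie the nucleus to the cytoskeleton. Capg (1.62), Iqgap1 (1.39), Msn (0.94) and Vasp (0.63) encode regulators of actin, and Anxa5 (1.69) and S100a10 (1.56) encode membrane-binding proteins. Mir144 (0.98) and Mir451a (0.76), which are made from a shared precursor and are abundant in red cells, also rose.

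A further test was planned before the result was seen. It asked whether the genes higher in KO-labelled TER119 positive cells tend to be lower in the WT TER119 positive than in the WT TER119 negative fraction. Of the 180 genes 27 (15%) were at least 1 log2 unit lower in WT TER119 positive than in WT TER119 negative cells, against a mean of 23.8 and a highest of 42 in 10000 random sets matched on expression (permutation p = 0.27). The test gave no excess. The WT fractions also differed in other cell types, such as neutrophil markers (median -4.90) and hepatocyte markers (median 4.29). Whether WT cells lower these genes as they become TER119 positive therefore cannot be told from it. Of the same genes 39 were at least 1 unit higher, against a mean of 32.0 (permutation p = 0.0915).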
